A study of Halobacterium salinarum NRC-1 with 8 samples.

How the data were processed

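Total RNA of 4 cultures was compared with a standard reference RNA on 8 spotted arrays, in Alexa 532 and Alexa 647, with the dyes exchanged on the 2 arrays of each sample, per the labels. Spot and background intensity values are linear scanner brightness, not corrected, with each dye scanned at a high and a low setting, per the file headers. A confidence score from the scanner accompanies each spot in the deposited files. It fell mostly where pixels were saturated, so it was not used to drop spots. The deposited value table holds log10 values that followed the 532 over 647 ratio of bright spots on every array (r from 0.906 to 0.953, slope from 0.82 to 0.89). Its column medians ran from 0 to 0.08. Its centring, its background treatment and the meaning of its zeros (54 to 2507 per array) and blanks are unknown. Its rows run along whole physical rows of the array, a match that the comparison with the scanner values bore out. The scanner software, filters and normalization of the authors are not given in the sources used here. The gene symbols came from the platform annotation given, in which 133 probes had 1 symbol, 0 had several and 2555 had none. All 133 symbols also occur in the RefSeq gene table given, which was used for names only.

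From the intensity values, R 4.3.3 and limma 3.58.1 computed log2 ratios. Background was corrected by normexp with an offset of 50 on spot median and background median intensity of the high scan. Each array was normalized by global loess with a span of 0.3. Control spots were not told apart from others and none was left out. The ratio was turned to sample over reference on every array, the 4 spots of a probe were averaged, and the 2 arrays of a sample were averaged before the fit, since they carry the same RNA. Arrays of the same dye orientation correlated at 0.15 to 0.60 over all probes. Arrays of opposite orientation, after turning, correlated at -0.17 to 0.15, so the ratios of single arrays shared little between orientations. A constant dye bias of a probe cancels in the mean of a pair.

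The fit was additive in oxygen and light over 4 samples, with effects coded so that the intercept is the mean over the reference, and with Benjamini-Hochberg adjustment at 0.05. It leaves 1 residual degree of freedom, which also holds the interaction. Each SE given with n = 4 samples is the moderated SE of limma, which borrows spread from all probes. Gene lists of at least 3 measured members were tested by camera with a preset correlation of 0.01 against the 133 named genes. Of 23 lists fixed before the data were examined, 8 had no measured member. Another 8 lists were added once the array's symbols were known and before any expression value was compared, and 15 lists in all were tested. The gene panB was taken out of the heat shock list, which had caught it by its prefix. The background of named genes was chosen after the first fit and before list results were seen.

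A probe counted as above background on an array when the median over its 4 spots exceeded the local background by 1 SD of its pixels. This rule was chosen after counts under 1 SD and 2 SD were seen. Under 2 SD, 80 named genes lay above background on at least 1 array and 33 on all 8, against 103 and 48. Where a probe was above background in only 1 arm, a fold was estimated per channel after loess and Aquantile, open to dye bias. Values in the dim arm were raised, where lower, to the lowest level of any probe above background on that array. Arrays at background in the bright arm were kept, so the estimate is not a strict bound. Saturation was set at 65535. A probe saturated or at background in both arms was given no fold.

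Named genes followed a rule fixed before the data were examined: the deleted genes, the 10 named genes with the largest values each way per comparison (of the same sign in both parts of the design for oxygen and light), up to 4 members per list, the 5 largest interactions each way, and a short set of light and oxygen genes where measured. As none passed the test, values are given and not calls. sdhC, the 4 genes arcA, arcC, carA and carB as a group, and the probes of a single array series were singled out after their values were seen. Unnamed probes are counted and not listed.

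The steps were tested on simulated data. In the simulation of the fit, changes were added to simulated sample values on the log2 scale, with independent normal noise. Its shares therefore leave out any loss in the processing. For oxygen, with 200 of 2688 probes changed and variances drawn from the fitted prior, 50 draws recovered on average 0.23% of changes of 0.5 on the log2 scale, 82.1% of changes of 1 and 99.3% of changes of 2. For light these shares were 0.42%, 74.5% and 98.9%. For the reference comparison they were 81.6%, 99.3% and 99.9%. In single draws the share of changes of 1 recovered ran from 0 to 97% for oxygen and from 0 to 98.5% for light, and for the reference comparison the share of changes of 0.5 ran from 0 to 99%. With changes of 1, false calls averaged 6.46%, 6.03% and 7.74% of calls for oxygen, light and reference, and reached 16.7%, 15.5% and 33.1% in single draws. A spike of 2 on the log2 scale into the raw sample channel of the low oxygen arrays came back as a median of 1.81 upward and -1.45 downward. The processing thus understated folds for the 200 spiked probes. These lay in the upper range of mean intensity, short of the brightest, and spots without net signal were left unspiked. Dimmer probes were not covered. In the list test, for the reference comparison, a list of 7 genes shifted by -0.3 was called in 100 of 100 draws and an unshifted list in 2. For light, a list shifted by -0.2 was called in 80 of 100 draws, by -0.1 in 31, and an unshifted list in 6. For oxygen these were 83, 33 and 5. These genes were simulated as independent. Here a list counted as called at an unadjusted camera p under 0.05, with 2 lists per draw. The lists of the data were called at an adjusted p under 0.05 over 15 lists. The shares of shifted lists called thus overstate what that test could detect.

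Alternatives fixed before the data were examined covered background correction, normalization, spot averaging, a filter on dim probes, the deposited values, the eBayes prior, an array-level fit, the covariate, the array series, the list test, a rule on size, and leaving out each sample or array. Alternatives chosen after seeing the data were loess within printed sets, rescue of saturated spots from the low scan, spot mean intensity, probes above background in both arms, an all-probe list background, the mean over the reference alone in the fit, the purine list without purB and purF, and gene lists without each sample. The list of flagella and chemotaxis genes held only transducers and che genes among the named probes. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.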

Results

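Transcript levels were measured in Halobacterium salinarum NRC-1, a salt-loving archaeon, in a strain lacking ura3 and the gene VNG1296C. Cultures of 50 mL in 125 mL flasks were grown in rich medium to mid-log phase in 4 conditions. High oxygen meant shaking at 210 rpm and low oxygen shaking at 100 rpm, each in light and in dark. Each condition was represented by 1 RNA sample on 2 arrays with the dyes exchanged, so 8 arrays gave 4 samples. Each array set the sample against a standard NRC-1 mid-log reference RNA (optical density 0.5 to 0.6). The arrays held 2688 probes in 4 spots each, of which 133 carried a gene symbol and 2555 did not. In the sample channel, 103 of the 133 named genes lay above background on at least 1 array and 48 on all 8. Between 670 and 1199 probes per array lay above background. With 1 sample per condition, p-values measure the spread left by an additive model of oxygen and light, with 1 residual degree of freedom. Both the 1 RNA sample per condition and the number of arrays limit the precision.

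The deleted genes come first. The probe for pyrF (probe 4991), the orotidine phosphate decarboxylase gene also called ura3, gave a log2 ratio of sample over reference below 0 on 8 of 8 arrays. It was not well above background in either channel on any array, so no fold is given, no test of it carries weight and the probe does not check the labels. In the authors' deposited values it lay below 0 on 5 of 8 arrays. Whether the probe lies inside the deleted part is not stated in the sources used here. VNG1296C was not analysed here.

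The mean of the 4 samples over the standard reference shows how the deletion strain, in these cultures, differed from the reference RNA. Genes of purine synthesis lay below the reference as a list. All 7 measured members had negative means, and the list averaged -0.30 on the log2 scale (camera adjusted p = 0.00878). The adjusted p was 0.854 with an estimated correlation, which rests on 1 residual degree of freedom. The list mean was below 0 on 8 of 8 arrays, from -0.62 to -0.11. Among the members, purL had a log2 ratio of -0.49 ± 0.08 (SE, n = 4 samples) and purD -0.41 ± 0.07, with the sample channel above background on 7 and 5 arrays. For purF, the first enzyme of the pathway, the ratio was below 0 on 8 of 8 arrays. Its sample channel lay above background on 2 arrays, both in light, and its reference channel on 6, so no exact ratio is given. The member purB was not well above background on any array. Without purB and purF the list mean was -0.24 (adjusted p = 0.208), and over named genes above background, with purF, it was -0.29 (adjusted p = 0.00262). The values were -0.18 ± 0.07 for guaB, an IMP dehydrogenase of guanine nucleotide synthesis, -0.10 ± 0.08 for purM and -0.05 ± 0.07 for purE. The sample channel of purE lay above background on 1 array, and its mean kept its sign in 23 of 26 other settings. No member passed the test over all probes, and 3 passed when adjusted over the list alone. This list was written after the array's symbols were seen and before any expression value was compared. With the mean alone in the fit, without oxygen and light terms, the adjusted p of the list was 0.0665, and with a trend and robust prior it was 0.0784. In the fit of the mean alone it was 0.258 without the high oxygen dark sample and 0.233 without the low oxygen dark sample.

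Other named genes had values well away from the reference without passing the test. The lowest among those above background were phoU, a regulator of phosphate uptake, at -0.62 ± 0.09 (SE, n = 4 samples), and argH, an arginine synthesis gene, at -0.52 ± 0.07. The highest were carB at 0.47 ± 0.08, arcC at 0.37 ± 0.07, gdhA2 at 0.37 ± 0.06 and arcA at 0.28 ± 0.07. The genes carA (0.23 ± 0.07) and carB encode carbamoyl phosphate synthetase, arcA and arcC act in arginine fermentation, and gdhA2 encodes a glutamate dehydrogenase. The sample channel lay above background on 5 arrays for argH, 4 for carB, 6 for gdhA2 and all 8 for phoU, arcA, arcC and carA. The chaperone gene dnaK, above background on all 8 arrays, stood at 0.23 ± 0.07. The probe for dnaJ, at 0.25 ± 0.07, was above background only on the 5 arrays with the higher array numbers, and its value ran from 0.11 to 0.75 over the other settings. In pyrimidine synthesis, 3 of 5 genes passed when adjusted over the list alone: carA and carB above the reference, and pyrF, at background and so given no weight, below it. The camera adjusted p of that list was 0.481. The reference came from another strain and culture and had no spread of its own, so strain and culture cannot be told apart in this comparison.

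**Figure D1:**
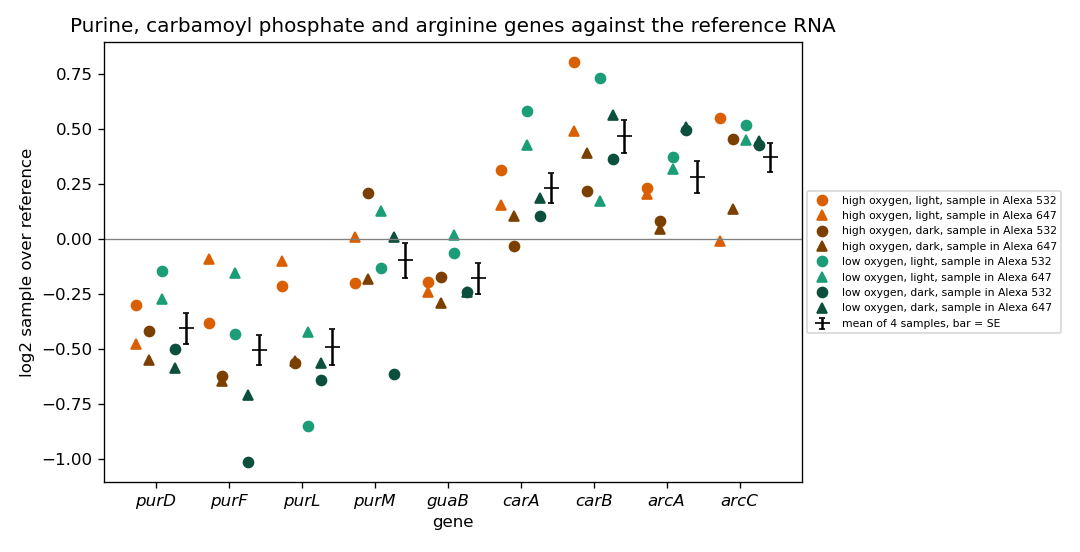
Log2 ratio of sample over reference for 9 named genes on each of 8 arrays, with circles for samples labelled with Alexa 532, triangles for Alexa 647 and colours for the 4 conditions. Black marks show the mean of 4 samples with its SE; purL lies at -0.49 and carB at 0.47. The sample channel of purF was above background on 2 arrays.

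limma with Benjamini-Hochberg adjustment called 0 of 2688 probes against the reference. At an unadjusted p under 0.05 there were 618 probes, 268 higher and 350 lower, where 134.4 would be expected by chance, and leaving out a sample or an array gave 423 to 719. Across probes, the ratio from the Alexa 532 arrays against that from the Alexa 647 arrays gave r = -0.04 over all 2688 probes. It gave 0.17 over the 501 probes above background on every array and 0.07 over the 133 named genes. Arrays of the same RNA in opposite dyes thus shared little of this ratio. The count of called probes depended on the setting. It was 147 without background subtraction, 30 with median centring, 91 with the median of the spots, 133 with the mean alone in the fit, 505 when each array was kept with the sample as a random block, and 770 from the authors' deposited values. The random block fit rests on a consensus correlation of -0.42 between the 2 arrays of a sample. Over the 1364 probes above background, 24 were called.

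The oxygen comparison asks how transcripts differed between low and high oxygen, averaged over light and dark. No named gene passed the test, so the following are values. Above background in all 8 arrays, arcA stood at 0.28 ± 0.15 (log2 low minus high, SE, n = 4 samples), glnA, a glutamine synthetase saturated on 1 array, at 0.24 ± 0.14, and leuS, a leucyl-tRNA synthetase, at 0.22 ± 0.14. On the lower side, gdhA1, a glutamate dehydrogenase, stood at -0.36 ± 0.13. The probe for pyrI, a subunit of aspartate carbamoyltransferase, was saturated on 4 arrays in the sample channel and 5 in the reference channel, so no value is given. The probe for csg, the cell surface glycoprotein, was saturated in both channels on 8 of 8 arrays and has no fold. The probe for hisB, which had the highest oxygen value among named genes, was not well above background on any array. In sdhC, a succinate dehydrogenase subunit, both the sample and the reference channel lay above background on the 3 arrays of the first number series. Neither channel did on any other array, so no fold is given.

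Among the gene lists, none passed for oxygen. Of 6 citric acid cycle genes, 4 had values above 0 (list mean 0.04, camera adjusted p = 0.960), and of 11 chemotaxis genes, 7 transducers and 4 che genes, 8 had values below 0 (list mean -0.05, adjusted p = 0.773). The citric acid cycle mean kept its sign in 23 of 27 other settings and the chemotaxis mean in 24 of 27. Purine synthesis averaged -0.05 with 3 values up and 4 down (adjusted p = 0.960), and this mean had no settled sign: with oxygen alone in the fit it was -0.25 without the low oxygen light sample and 0.14 without the low oxygen dark sample. limma called 0 probes for oxygen, with 163 at an unadjusted p under 0.05, 73 higher and 90 lower, where chance would give 134.4. When a sample or an array was left out, this unadjusted count ran from 68 without the high oxygen dark sample to 295 without the low oxygen dark sample. Over the 1158 probes above background in both arms it was 18, where chance would give 57.9. The p-values thus ran high over these probes, and the 0 calls among them do not show an absence of change. The smallest adjusted p was 0.735. The authors' deposited values gave 2 called probes. The array numbers fall into 2 series, and both high oxygen light arrays and 1 high oxygen dark array lie in the first, so series and oxygen are partly confounded. With a term for the series, on technical error alone, 0 probes were called.

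The light comparison asks how transcripts differed between light and dark, averaged over the 2 oxygen levels. Purine synthesis genes were higher in light as a list, with 6 of 7 members above 0 and a mean of 0.23 (camera adjusted p = 0.0310, and 0.977 with an estimated correlation). The largest value came from purB, at background on every array, and the next from purF, at background on every dark array. Without these 2 members the list mean was 0.10 (adjusted p = 0.575), so the call rests on them. The transducers, receptor proteins that pass signals to the flagellar motor, were lower in light as a list, with 5 of 7 below 0 and a mean of -0.13 (adjusted p = 0.0310, and 0.977 with an estimated correlation). The list of all 11 chemotaxis genes, fixed before the data were examined, did not pass (adjusted p = 0.341), and its 4 che genes averaged 0.06 with 3 above 0. No member of either list passed over all probes or over the list alone. Because purF was not well above background on any dark array, and was above it on 2 light arrays, only a sample-channel estimate is given. In that channel purF stood 1.29-fold higher in light (limma adjusted p of the ratio = 0.683). The light mean includes arrays at background, so this is not a strict lower bound. The members purD and purL stood at 0.21 ± 0.14 and 0.19 ± 0.16 (log2 light minus dark, SE, n = 4 samples), and the member below 0 was purE. Among the transducers, htr8, above background on 2 arrays, stood at -0.38 ± 0.13, htr1 at -0.06 ± 0.13 and htr2 at -0.05 ± 0.13, and htr4, htr7 and htr18 were not well above background on any array.

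The light calls of both lists depended on the setting. Over probes above background in both arms, the adjusted p was 0.136 for purine synthesis and 0.164 for the transducers, and against a background of all probes it was 0.339 for each. Within the first array series, on the Alexa 532 arrays, the light value of the purine list was 0.13, and within the second series it was 0.38. The transducers gave -0.27 and -0.08. Both low oxygen samples lie in the second series, so its values are also the light effect in low oxygen. In high oxygen, over both dyes, the light value was 0.08 for the purine list and -0.18 for the transducers. When each of the 4 samples or 8 arrays was left out in turn, the purine call was kept in 4 of 12 fits and the transducer call in 3 of 12. With light alone in the fit the adjusted p of each list was 0.0253 over all 4 samples. In that fit the purine list mean ran from 0.13 without the low oxygen dark sample to 0.33 without the high oxygen dark sample. The purine list had an adjusted p of 0.112 without the low oxygen light sample and 0.556 without the low oxygen dark sample. The transducers had 0.622 without the high oxygen dark sample and 0.703 without the low oxygen light sample. Both lists were written after the array's symbols were seen. Elsewhere, carA stood at 0.28 ± 0.14 in light over dark, and cbiT and hemA, of cobalamin and haem synthesis, at -0.26 ± 0.13 and -0.21 ± 0.14. The probes for bat, a regulator of bacteriorhodopsin synthesis, and hop, the halorhodopsin gene, were not well above background on any array. psmA, a proteasome subunit, stood at -0.03 ± 0.15. limma called 0 probes for light, with 190 at an unadjusted p under 0.05, 122 higher and 68 lower, where chance would give 134.4. When a sample or an array was left out, this unadjusted count ran from 102 without the Alexa 647 low oxygen dark array to 289 without the high oxygen light sample. Over the 1118 probes above background in both arms it was 7, where chance would give 55.9. Here too the p-values ran high, and the 0 calls among these probes do not show an absence of change. The smallest adjusted p was 0.683. Across probes, the light effect from the Alexa 532 arrays against that from the Alexa 647 arrays gave r = 0.01 over all 2688 probes. It gave -0.18 over the 501 probes above background on every array and -0.05 over the 133 named genes. Arrays of the same RNA in opposite dyes thus did not repeat the light effect across probes.

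The oxygen by light interaction and the simple effects have 1 sample per condition and no test. Across genes, which are not independent replicates, the oxygen effect in light correlated with that in dark at r = 0.04 over all 2688 probes and 0.15 over the 501 probes above background on all 8 arrays. The light effect in high against low oxygen gave r = 0.09 and -0.05. Leaving out 1 array at a time, r over all probes ran from -0.175 to 0.219 for oxygen and from -0.0906 to 0.169 for light. For arcA the oxygen value was 0.13 in light and 0.44 in dark. For gdhA1 it was -0.38 in light and -0.33 in dark. For htr8 the light value was -0.37 in high oxygen and -0.38 in low oxygen, but its sample channel lay above background on only 2 arrays. The median technical SE of a simple effect was 0.243 and of the interaction 0.344, from the dye-swapped pairs. For an oxygen or light effect averaged over the other factor it was 0.172. The median moderated SE of these averaged effects in the fit was 0.139, below that technical SE. In 71 probes the interaction reached 1 in size, but in only 3 of the 1364 probes above background on at least 1 array. The count of 71 became 9 without background subtraction and 649 with plain subtraction. The highest named value, in gatC, and 9 others among the 10 most extreme came from probes above background on at most 2 arrays.

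**Figure D2:**
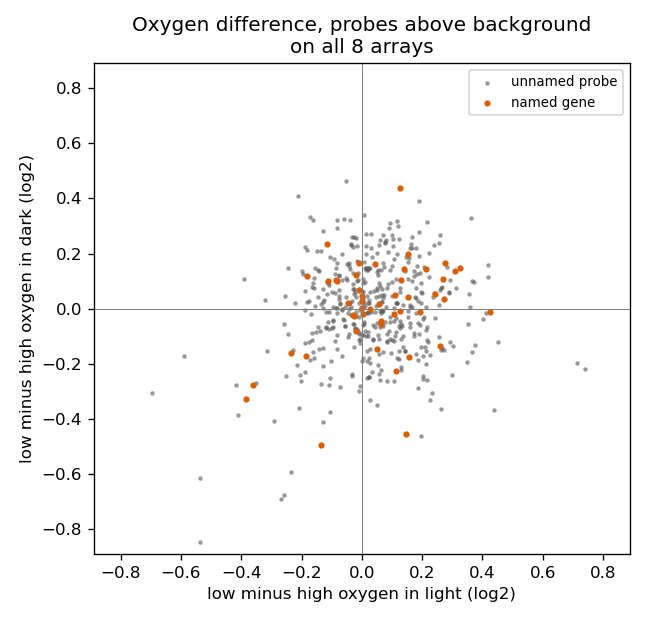
Log2 difference of low minus high oxygen in light (horizontal) against the same difference in dark (vertical) for the 501 probes above background on all 8 arrays, with named genes in orange. The points scatter around 0 on both axes, with r = 0.15 across probes.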

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

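These results were picked out because both dye-swapped differences between low and high oxygen went one way in light and both went the opposite way in dark. The difference was not tested, as each condition has 1 sample. Both high oxygen light arrays but only 1 high oxygen dark array lie in the first array series, and all low oxygen arrays lie in the second. The oxygen effect in light is thus fully confounded with the series and that in dark partly, so the series cannot be told apart from a difference between light and dark. Of 33 named genes examined, 5 met this. Signs falling at random would give 12.5%, or 4.125 genes. Some of the 33 were named for having the same sign of the oxygen value in light and in dark. Those could not meet it, so 12.5% is not an exact chance rate. The oxygen effect in light less that in dark was 0.60 in phoU, with a technical SE of 0.36, from 0.15 in light and -0.46 in dark. It was -0.39 with a technical SE of 0.28 in lysS, a lysyl-tRNA synthetase gene, and 0.34 with a technical SE of 0.29 in psmA, a proteasome gene. In carB, a carbamoyl phosphate synthetase gene, it was -0.35 with a technical SE of 0.36, and in purD, a purine synthesis gene, 0.24 with a technical SE of 0.28, both within 1 technical SE of 0.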

How the results depend on the processing

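The 4 samples, 1 residual degree of freedom and dim spots limit these results: 501 of 2688 probes lay above background on all 8 arrays. The alternative of keeping spots with a bad flag was not run, since no such flag was found. The cause of each change below was not tested. Leaving the other factor out moved no count past 1.5 times. Aquantile between arrays changes only mean intensities and leaves the ratios as they are. Its values were therefore those of the main fit by construction, and it tests nothing here, though it is counted among the other settings. Settings chosen after seeing the data are the loess within printed sets, the low scan for saturated spots, spot mean intensity, the all-probe background, the mean alone in the fit, the purine list without purB and purF, gene lists without each sample and the probes above background in both arms.

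Probes called against the reference (0) became 147 without background subtraction, 30 with median centring, 91 with the median of the 4 spots, 34 without the dimmest 25% of probes, 770 with the authors' deposited values, 505 with each array kept and the sample as a random block, 133 with the mean alone in the fit, 86 with the low scan for saturated spots and 24 over probes above background. Leaving out a sample or an array gave 0 to 130: 121 without the low oxygen light sample, 130 and 80 without either of its arrays, 91 without the first high oxygen dark array, and at most 1 otherwise. Oxygen gave 2 with the deposited values, and leave-one-out gave 0. For light, 1 probe met the rule of a size of at least 1 with the same sign in both parts, and leave-one-out gave 0 to 2, with 2 without the high oxygen light sample. The probe for pyrF, at background, lay below the reference on 8 arrays, on 5 with the deposited values and on 7 or 8 with the other settings run.

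Lists called for light (2) became 0 without background subtraction, with the trend and robust prior, with an estimated correlation, with all probes as background, with loess within printed sets, with spot mean intensity and over probes above background. They became 1 with plain subtraction, median centring, the median of spots, the dimmest 25% left out, the deposited values and the random block. Leave-one-out gave 0 to 2. Lists called for oxygen (0) became 1 with median centring. Lists called against the reference (1) became 2 with the deposited values, and 0 with the trend and robust prior, with an estimated correlation and with the mean alone in the fit. Leave-one-out gave 0 to 1.

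The r of the oxygen effect in light against dark (0.04) was 0.113 without background subtraction, 0.278 with median centring, -0.00089 without the dimmest 25%, -0.0347 with the deposited values and -0.107 within the second array series. Leave-one-out of arrays gave -0.175 to 0.219. The r of the light effect (0.09) was 0.00966 without background subtraction, 0.00706 with plain subtraction, -0.0625 without the dimmest 25%, 0.0245 with the deposited values, 0.0136 with loess within printed sets and -0.0583 over probes above background. Leave-one-out of arrays gave -0.0906 to 0.169. Interactions of at least 1 in size (71) numbered 9 without background subtraction, 649 with plain subtraction, 31 without the dimmest 25%, 2 with the deposited values and 3 over probes above background. Leave-one-out of arrays gave 89 to 195.

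With the deposited values, 4 named genes turned sign against the reference and passed the threshold: pyrI at 0.21, gdhB at 0.27, secY at 0.23 and hutG at -0.14. Of these, pyrI, gdhB and secY were saturated on some arrays in both channels of the scanner data and hutG was at background on every array, so their signs are not settled. Over the other settings, 146 of 3417 values of single named genes against the reference passed with the sign of the main fit. No named gene passed for oxygen or light under any setting run. When a sample was left out, the fit kept only the tested factor, or only the mean, so the model and the samples changed together. Its arm then held 1 sample, which was assumed to vary like the other.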

Other observations

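The tests of the dim probes below were chosen after the result was seen, and both groups of reference genes were chosen for weighing after their values were seen. Other gene groups gave values without a call. The 12 aminoacyl-tRNA synthetase genes averaged 0.06 over the reference on the log2 scale, with 7 above and 5 below (camera adjusted p = 0.481). The 6 histidine synthesis genes averaged -0.06, the 5 thiamine and NAD synthesis genes -0.14, and the 6 cobalamin genes 0.02. The 4 genes of glutamate and ammonium metabolism averaged 0.07 over the reference and -0.06 in low over high oxygen. In light over dark, 5 of 6 cobalamin genes had values below 0 (mean -0.07, adjusted p = 0.524).

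Oxygen effects in light and in dark did not correlate across probes. Array measurement noise is a candidate explanation. The oxygen effect from the Alexa 532 arrays against that from the Alexa 647 arrays gave r = -0.16 over probes above background on all 8 arrays and -0.09 over those on at least 1, so the 2 sets of arrays of the same RNA did not repeat it. Dilution by dim probes stays open, at r = 0.15 over probes above background on all 8 arrays. The array series of the high oxygen arrays also stays open: with the dark effect within the second series, r was 0.26 over probes above background on all 8 arrays and 0.09 over those on at least 1. A true difference between light and dark was not tested.

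Purine synthesis genes lay below the standard reference as a list, with a camera adjusted p of 0.00878, and of 0.854 with an estimated correlation. Among 10000 random lists of 7 probes matched on mean intensity, the list mean of -0.30 fell at percentile 0.08. The list was weighed as the 1 called of the 15 tested, so this percentile is partly set by that choice. The random lists themselves averaged -0.02, which argues against an intensity trend left after loess as the source of the full -0.30. A constant dye bias cancels in the mean of a pair, so it does not account for the -0.30. The list mean was below 0 on 8 of 8 arrays across both dye orientations, a count partly set by the same choice of list. The strain, the culture and the preparation of the reference stay open, as the design sets them together. In the first array series the list mean was -0.26 and in the second -0.33.

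The genes arcA, arcC, carA and carB had a mean of 0.34 over the standard reference. They were grouped after their values were seen, the group had no list test, and none of the 4 passed the test over all probes. A constant dye bias cancels in the mean of a pair, so it does not account for the 0.34. Their mean was above 0 on 8 of 8 arrays, but the genes were chosen for high values on these arrays. That choice partly sets the sign count, so no conclusion is drawn from it. The mean of the 4 genes fell at percentile 100 among random lists matched on intensity, and the same choice means that this excludes no intensity trend. The strain and the culture stay open here too, untested.

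In 3 probes, among them sdhC, both channels lay above background on each of the 3 arrays of the first number series and on none of the 5 others. In 13 probes, among them cbiG, citZ and dnaJ, both channels did so on the 5 arrays of the second series alone.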
